A study of Mus musculus with 9 samples.

How the data were processed

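The deposited table held FPKM per gene for 9 lung libraries, and per the labels it came from poly(A) RNA extracted with Trizol and prepared with NEBNext Ultra. Reads had been mapped by the authors to GRCm39, and the aligner and the quantification tool are not given in the sources used here. The table listed 21884 genes, of which 13076 carried a symbol, 8730 were named from a reference annotation by Ensembl identifier and 78 had no symbol. That annotation was of another build, so names were taken from it and coordinates were not used. In all, 3610 genes were at 0 in every library.

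FPKM values were filtered to at least 0.5 in at least 3 of the 9 libraries, which kept 12982 genes, and tested as log2(FPKM + 0.5). Fold changes are on this log2(value + pseudocount) scale, which understates the change of low genes. Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a variance trend) in 1 fit of all 9 libraries with 6 residual and a median of 2.79 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. With 3 libraries against 3, an exact permutation test cannot go below 0.1. The 34 gene lists (cell types, pathways, other tissues, handling and clock) were tested with camera and with fry. A list was tested on its members past the filter, which were few for some lists. They were 5 of 12 eosinophil, 6 of 14 mast cell and basophil and 3 of 9 skeletal muscle genes. Of thymus and lymphoid tissue genes, called thymus genes below, 3 of 9 passed. Genes of other tissues could pass the filter through the OVA+PM2.5 libraries alone. Camera was run at a preset inter-gene correlation of 0.01 and with an estimated correlation. Fry called 2 lists in OVA against Naive, interferon and immediate early genes. In OVA+PM2.5 against OVA it called 5: type 2 cytokines and receptors, NRF2, estrogen-related receptor, oxidative phosphorylation and erythrocyte genes. In OVA+PM2.5 against Naive it called 5: type 2 cytokines and receptors, interferon, estrogen-related receptor, immediate early and clock genes. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

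The test, the filter, the gene lists, the rule for naming genes, the 2-group fits and the other scalings were chosen before the data were examined. The rule named Esrrg and Pde3b, the 6 higher and 6 lower genes of largest fold change past the threshold with non-overlapping groups and a mean FPKM of at least 1, and the 1 or 2 members with the smallest p of each list. A few genes that the rule selected are not reported here. Where no gene passed in a direction, the 6 smallest p were named as values. Other genes with single-library values, among them Isg15, Il4, Il13, Muc5ac, S100a8, Rag1, Dntt, Myl7 and Scgb1a1, were chosen after the values had been seen. The limit of 10 times the highest Naive or OVA library, at an FPKM of at least 5, was also set after they had been seen.

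FPKM steps between libraries gave whole fragments for 17297 of 17298 genes above 0 in at least 2 libraries (99.99%, within 0.001 of a whole number). Recovered totals were 10801553 to 15458690 fragments, with relative depths of 0.787 to 1.02. In a check on 2965 simulated genes 100% were recovered in proportion, and of 2711 perturbed genes 0% came out whole. These fragments served only for depth, for an added voom fit and to look for libraries deposited more than once, where the closest pair, Naive replicates 2 and 3, still differed by a mean chi-square of 38.5 per gene, so every library counted as 1 replicate.

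Replicate numbers are shared by the groups, and deviations of same-numbered libraries correlated at −0.171 to 0.278, with 3 of 9 pairs over 0.1, so the numbers were not treated as pairs. In a self-test with 200 changed genes among 12982, limma found 72.6%, 74.6% and 75% of changes of 2 log2 units in the 3 comparisons and 25.8%, 34.2% and 33.6% of changes of 1, with means of 5.05, 73.55 and 67.5 false calls. The 2-group fit of OVA against Naive found 85.7% and 46.2%, with 15 false calls. A shifted list was found in 100% of draws, with means of 0.3, 0.15 and 0.25 other lists called. These means cannot show how often lists are called by chance in the real libraries, where genes of a list move together. Among lists called after OVA, the estimated correlation ran from 0.065 for NRF2 genes to 0.89 for proliferation genes. Other splits of the real libraries called up to 20, 15 and 15 lists in the 3 comparisons.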

Results

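Lung mRNA was profiled in 9 BALB/c mice, given as male in the labels, 3 in each of 3 groups: Naive, ovalbumin (OVA) and OVA with fine particulate matter (OVA+PM2.5). Mice entered at 6 weeks of age and received saline, or 50 µg OVA with 1 mg aluminium hydroxide on days 0, 7 and 14 and then 400 µg intranasal OVA daily from day 21 to day 27. Particles of 2.5 µm were given as nasal drops daily from 7 days before the first injection, and lungs were taken on day 28. The series title names 2 genes, the nuclear receptor Esrrg and the cAMP-degrading phosphodiesterase Pde3b, so both were examined in every comparison. The labels number the mice within each group, and p-values measure the spread between these samples.

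The largest differences between libraries were transcripts of tissues other than lung parenchyma. Skeletal muscle genes dominated OVA+PM2.5 replicate 1, where 8 of 9 list members (88.9%) exceeded 10 times the highest Naive or OVA library, with the muscle actin Acta1 at 11980 FPKM. Atrial and cardiac genes were raised in replicate 2, with 12 of 14 members (85.7%) past the same limit and the atrial myosin light chain Myl7 at 2650 FPKM. Brown fat genes were raised in replicate 3, with 6 of 7 members (85.7%) past it and the uncoupling protein Ucp1 at 1308 FPKM, next to 4 of 9 skeletal muscle members (44.4%). Of 388 genes raised in at least 1 OVA+PM2.5 library, 325 were raised in exactly 1 and 1 gene, the muscle coregulator Perm1, in all 3. The surfactant gene Sftpb stood at 8.45 FPKM in replicate 1, 554 in replicate 2 and 35.8 in replicate 3, against 977 ± 179 in OVA. The club cell secretoglobin Scgb1a1 took 2.07% to 3.77% of recovered fragments in Naive, 3.85% to 9.79% in OVA and 0.0%, 4.16% and 0.33% in OVA+PM2.5 replicates 1, 2 and 3. Naive libraries were not free of other tissue: in replicate 1 the thymus list had 3 of 9 members (33.3%) raised, with the recombination genes Rag1 at 79.8 FPKM and Dntt at 51.9 FPKM, and in replicate 3 the adipose list had 2 of 7 (28.6%), as in OVA+PM2.5 replicate 1, with the carbonic anhydrase Car3 at 73.6 FPKM.

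Correlations of log2 values followed the same division. Pairs of Naive libraries correlated at 0.956 to 0.972 and pairs of OVA libraries at 0.926 to 0.957, while pairs of OVA+PM2.5 libraries reached 0.757, 0.799 and 0.815. OVA+PM2.5 replicate 2 correlated at 0.868 to 0.932 with the Naive and OVA libraries, replicate 3 at 0.751 to 0.791 and replicate 1 at 0.638 to 0.699.

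**Figure D1:**
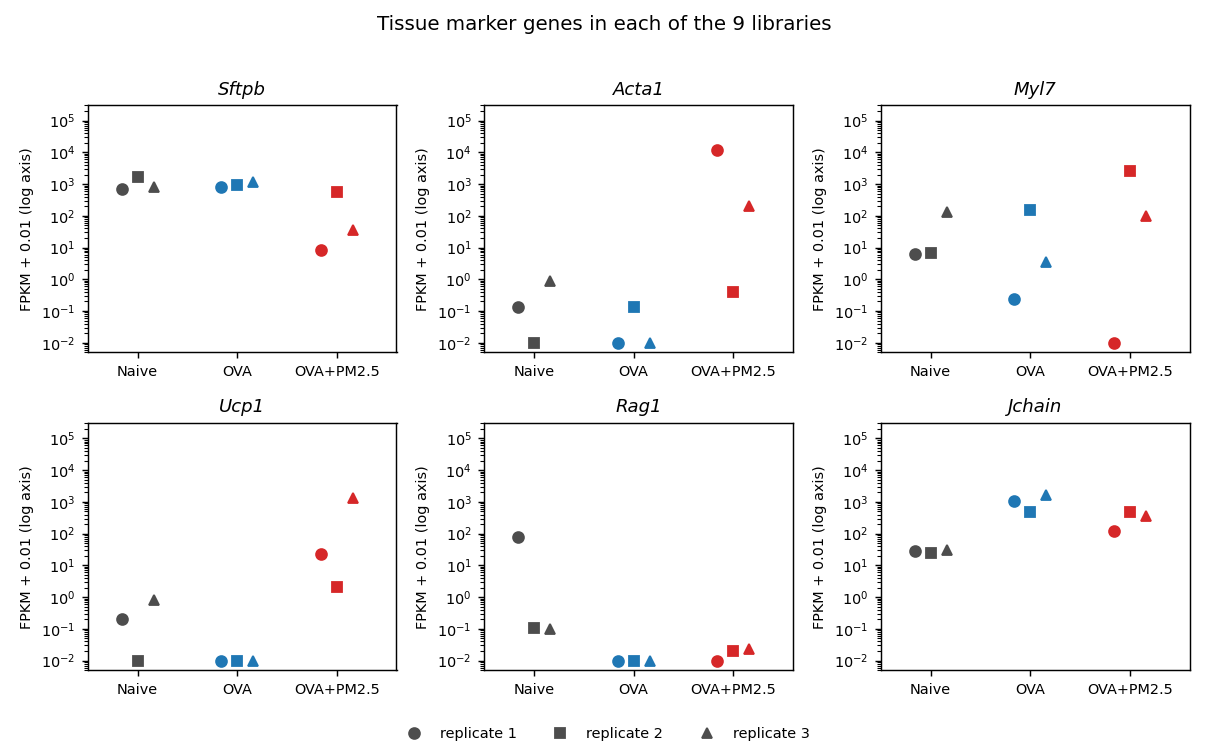
FPKM of Sftpb, Acta1, Myl7, Ucp1, Rag1 and Jchain on a logarithmic axis in Naive, OVA and OVA+PM2.5 lungs, 1 point per library, with circles, squares and triangles for replicates 1, 2 and 3. Acta1 reached 11980 FPKM in OVA+PM2.5 replicate 1, Myl7 2650 in replicate 2 and Ucp1 1308 in replicate 3.

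Ovalbumin sensitisation and challenge provokes allergic airway inflammation, in which antibody-secreting cells and granulocytes gather around the airways and the epithelium is remodelled. At the level of gene lists, plasma cell, neutrophil, ciliated, club cell, xenobiotic and oxidative defence genes stood higher in OVA than in Naive lungs, and interferon-induced, immediate early, endothelial and red cell genes lower. Camera called these lists with a preset inter-gene correlation and none of them with an estimated one (adjusted p 0.239 or more). The orphan nuclear receptor Nr4a1, an activation-induced transcription factor, fell to 2.57 ± 0.427 FPKM from 23.2 ± 3.09 (log2 fold change −2.95, adjusted p 0.0236). The natural killer cell receptor gene Ncr1 fell to 0.304 ± 0.271 FPKM from 7.00 ± 2.64 (−3.22, adjusted p 0.0377).

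With limma on all 9 libraries, Ncr1 and Nr4a1 were the 2 genes past an adjusted p of 0.05, with 0 higher and 2 lower, against 1474 at an unadjusted p under 0.05. In 4363 genes (33.6%) the groups did not overlap, where 10% would on average by chance. Genes that move together can take this share far from 10% in any 1 grouping, so it does not measure the evidence for change. The 2-group fit of these 6 libraries, planned before the data were examined, called 895 genes, 387 higher and 508 lower, Ncr1 and Nr4a1 among them. Without Naive replicate 1, the library with thymus genes, the 2-group fit called 37, 10 higher and 27 lower. The wide spread of OVA+PM2.5 entered the 9-library variance, and with 1 weight per group (2.154 for Naive, 1.338 for OVA, 0.347 for OVA+PM2.5) the same 9 libraries gave 817. Leaving out a Naive library left 0 genes in limma (744, 1245 and 888 at an unadjusted p under 0.05 without replicates 1, 2 and 3), as did leaving out OVA replicate 2 or 3 (1187 and 1002). Without OVA replicate 1 there were 16 (13 higher, 3 lower), and without OVA+PM2.5 replicates 1, 2 and 3 there were 25 (3 and 22), 54 (16 and 38) and 5 (1 and 4). The median change over all genes was −0.11, and −0.5 after rescaling FPKM to a common sum. The split was 1 higher and 2 lower after median-ratio scaling and 5 higher and 13 lower after quantile normalization.

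The higher genes with the smallest p remained short of the threshold in the 9-library fit and passed it in the 2-group fit. The immunoglobulin joining chain Jchain, secreted with polymeric antibody, stood at 1063 ± 581 FPKM against 27.2 ± 3.02 (log2 fold change 5.10, adjusted p 0.0539). The poly(A) polymerase Tent5c, which stabilises immunoglobulin mRNA in plasma cells, stood at 33.1 ± 10.3 against 9.67 ± 1.55 (1.69, adjusted p 0.0663). Topaz1, known from germ cells, stood 2.14 higher (adjusted p 0.0570), the olfactory cation channel Cnga2 1.5 (0.0663), the ciliary gene Tmem232 1.26 (0.0861) and the PACAP receptor Adcyap1r1 1.23 (0.0768).

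Of 34 gene lists fixed before the data were examined, camera with the preset correlation of 0.01 called 13 (7 up, 6 down). With the correlation estimated from the data it called 0, with adjusted p of 0.239 or more. Interferon response genes formed the strongest group and were lower after OVA (median log2 fold change −1.53, adjusted p 1.62e-14, 0.239 with the estimated correlation). In the 2-group fit 13 of 16 members fell, and adjusted over the list alone 14 did in the 9-library fit. Ifit1, which binds foreign RNA, stood at 6.54 ± 2.45 FPKM against 35.8 ± 13.4 (−2.36, adjusted p 0.0570), and Ifi44 at 2.64 ± 0.95 against 16.7 ± 4.98 (−2.47, adjusted p 0.0663). The ubiquitin-like Isg15 lay between 8.59 and 10.9 FPKM in the OVA libraries and between 118 and 168 in the Naive libraries.

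Immediate early and heat shock genes, a list fixed to track tissue handling, were also lower (median −1.19, adjusted p 2.05e-06, 0.255 with the estimated correlation), with 6 of 11 members falling in the 2-group fit. Egr1, an early growth response factor, stood at 2.16 ± 0.542 FPKM against 14.6 ± 6.93 (−2.43, adjusted p 0.0570). The clock repressor Ciart stood lower, at −1 (adjusted p 0.219), while the circadian list as a whole was not called (median −0.52, adjusted p 0.486).

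B and plasma cell markers were higher (median 0.71, adjusted p 2.4e-06, 0.239 with the estimated correlation), with 4 of 10 members rising in the 2-group fit, the survival receptor Tnfrsf17 among them (7.76 ± 4.33 FPKM against 1.22 ± 0.294, 2.11, adjusted p 0.168). Neutrophil markers and chemokines were higher (median 2.72, adjusted p 3.49e-09, 0.493 with the estimated correlation). The resistin-like Retnlg stood at 139 ± 113 FPKM against 4.40 ± 3.78 (4.34, adjusted p 0.277) and the epithelial neutrophil attractant Cxcl5 at 3.85 ± 4.10 against 0.0962 ± 0.0529 (2.47, adjusted p 0.307). The list was higher in OVA replicates 2 and 3 and not in replicate 1: the calprotectin subunit S100a8 stood at 10.9, 619 and 969 FPKM in replicates 1, 2 and 3.

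Aryl hydrocarbon receptor and xenobiotic genes were higher (median 1.14, adjusted p 0.00233, 0.458 with the estimated correlation), with 3 of 9 members rising in the 2-group fit. The dioxin-inducible oxygenase Cyp1b1 stood at 8.84 ± 1.12 FPKM against 1.78 ± 0.103 (2.02, adjusted p 0.0870), and the aldehyde dehydrogenase Aldh3a1 at 12.0 ± 3.27 against 3.23 ± 1.78 (1.84, adjusted p 0.264). NRF2 and oxidative stress genes were higher too (median 0.58, adjusted p 2.49e-06, 0.239 with the estimated correlation), and 4 of 19 rose in the 2-group fit, among them the metallothionein Mt1 (1.71, adjusted p 0.197) and the thioredoxin reductase Txnrd1 (0.86, adjusted p 0.208).

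Airway epithelial lists were higher. Ciliated cell markers led (median 1.33, adjusted p 4.16e-06, 0.699 with the estimated correlation), with all 14 members positive and 8 rising in the 2-group fit. The axonemal genes Dnah9 (1.57, adjusted p 0.343) and Ccdc40 (1.53, adjusted p 0.362) had the smallest p. Club cell markers followed (median 1.11, adjusted p 0.0247, 0.717 with the estimated correlation), with 3 of 9 members rising in the 2-group fit. The tight junction gene Cldn10 stood at 13.5 ± 4.37 FPKM against 5.35 ± 0.771 (1.22, adjusted p 0.600). The haptoglobin gene Hp stood at 764 ± 217 against 347 ± 42.2 (1.11, adjusted p 0.644). Goblet cell and mucus genes were called (median 0.59, adjusted p 0.0146, 0.699 with the estimated correlation), with 7 of 9 members positive and none rising in the 2-group fit. Its median against the Naive mean was 0.401, 0.118 and 1.93 in OVA replicates 1, 2 and 3. Its members with the smallest p were the anion exchanger Slc26a4 (1.22, adjusted p 0.519) and the mucin glycosyltransferase Galnt12 (0.59, adjusted p 0.508). The mucin Muc5ac stood at 0.298 ± 0.269 FPKM.

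Lower lists came from vessels, blood and dividing cells. Endothelial markers were lower (median −1.21, adjusted p 0.00448, 0.717 with the estimated correlation), with 3 of 12 members falling in the 2-group fit, including the sialomucin Emcn (−1.84, adjusted p 0.269) and the receptor kinase Tie1 (−1.38, adjusted p 0.395). Erythrocyte genes were lower (median −1.39, adjusted p 0.00233, 0.699 with the estimated correlation), with the haemoglobin genes Hba-a2 at −1.87 (adjusted p 0.368) and Hbb-bt at −2.07 (adjusted p 0.343). Antigen presentation and dendritic cell genes were lower (median −0.75, adjusted p 0.0332, 0.717 with the estimated correlation), including the dendritic lineage factor Zbtb46 (−0.69, adjusted p 0.328), while the costimulatory gene Cd80 stood higher (0.70, adjusted p 0.362). Proliferation genes were lower (median −1.03, adjusted p 4.83e-05, 0.717 with the estimated correlation), and here the thymus-bearing Naive library weighed in: the replication clamp Pcna stood at 47.6, 19.5 and 21.6 FPKM in Naive replicates 1, 2 and 3 (−0.94, adjusted p 0.360) and the cell cycle kinase Cdk1 at 3.95, 1.1 and 1.01 (−1.18, adjusted p 0.362). The same library held the T cell coreceptor Cd8b1 at 143 FPKM against 2.75 and 4.28 (−2.31, adjusted p 0.538).

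Lists of type 2 inflammation were not called after OVA. In the 2-group fit 1 of 12 type 2 cytokine and receptor genes rose, 1 of 5 eosinophil markers rose, which was Prg2, and of 6 mast cell and basophil markers 1 rose and 2 fell, Cma1 among them. Type 2 cytokines and receptors had a median of −0.30 (adjusted p 0.854), with the Th2 chemokine receptor Ccr8 at 1.66 ± 0.744 FPKM against 0.646 ± 0.394 (0.90, adjusted p 0.409). The cytokine Il13 stood at 0.131 ± 0.146 FPKM and Il4 at 1.79 ± 0.385 against 0.986 ± 0.238. Type 2 chemokines had a median of −0.17 (adjusted p 0.465), although the monocyte attractant Ccl8 stood at 53.8 ± 31.0 FPKM against 11.9 ± 9.66 (2.23, adjusted p 0.310). Eosinophil markers, of which 5 of 12 passed the filter, had a median of −0.55 (adjusted p 0.682). The granule protein Prg2 stood at 1.64 ± 0.987 FPKM against 0.153 ± 0.132 (1.64, adjusted p 0.192). A median of so few members cannot show whether eosinophil transcripts rose or fell after OVA. Mast cell and basophil markers had a median of −0.71 (adjusted p 0.398), and the chymase Cma1 stood at 0.0820 ± 0.0712 FPKM against 2.86 ± 0.794 (−2.51, adjusted p 0.0588).

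The remaining lists were not called after OVA in the 9-library fit. In the 2-group fit camera also called oxidative phosphorylation down (adjusted p 0.0142, and 0.0417 without Naive replicate 1) and smooth muscle genes up (0.00324 and 0.0164), and only without that library T cell markers up (0.00918) and cAMP signalling down (0.0496). With the estimated correlation these were at 0.662 or more. In the 9-library fit medians were 0.19 for alternatively activated macrophage genes (adjusted p 0.263), with the chitinase-like Chil3 at 2.87 (adjusted p 0.368), and 0.21 for alveolar macrophage markers (0.306), with the protease Ctsk at 1.25 (0.328). IL-17 and acute inflammatory cytokines had a median of −0.01 (0.310), with the mucosal attractant Ccl20 at 1.65 (0.310), and T cell markers −0.49 (0.915). Estrogen-related receptor genes had a median of 0.02 (0.419), with Esrra at −0.65 (0.463), and oxidative phosphorylation −0.29 (0.263), with the complex I subunit Ndufa2 at −1 (0.530). Phosphodiesterases had a median of −0.06 (0.915), with the cGMP-specific Pde5a at −1.31 (0.368), and cAMP signalling −0.27 (0.0907), with the adenylyl cyclase Adcy8 at −1.10 (0.312). Smooth muscle genes had a median of 0.50 (0.0561), with the enteric actin Actg2 at 1.13 (0.429), and fibrosis and matrix genes −0.53 (0.122), with the growth factor Tgfb1 at −1.08 (0.271). Alveolar type 1 and type 2 markers had medians of −0.50 (0.642) and −0.52 (0.746), with Clic5 at −0.57 (0.677) and the surfactant regulator Etv5 at −1.02 (0.565). Cardiac, skeletal muscle, adipose and thymus genes had medians of −0.03 (0.681), −0.64 (0.975), −0.79 (0.854) and 0.10 (0.218), with the troponin Tnnc1 at −0.83 (0.849), the creatine kinase Ckmt2 at −0.64 (0.9), the lipid droplet gene Cidea at 1.74 (0.655) and the B cell attractant Cxcl13 at 2.43 (0.353). Median and camera direction differed in sign for 6 lists: both type 2 lists, eosinophil, IL-17, cardiac and adipose genes. The sign of the median depended on the scaling for both macrophage lists and for IL-17, estrogen-related receptor, cardiac and thymus genes.

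**Figure D2:**
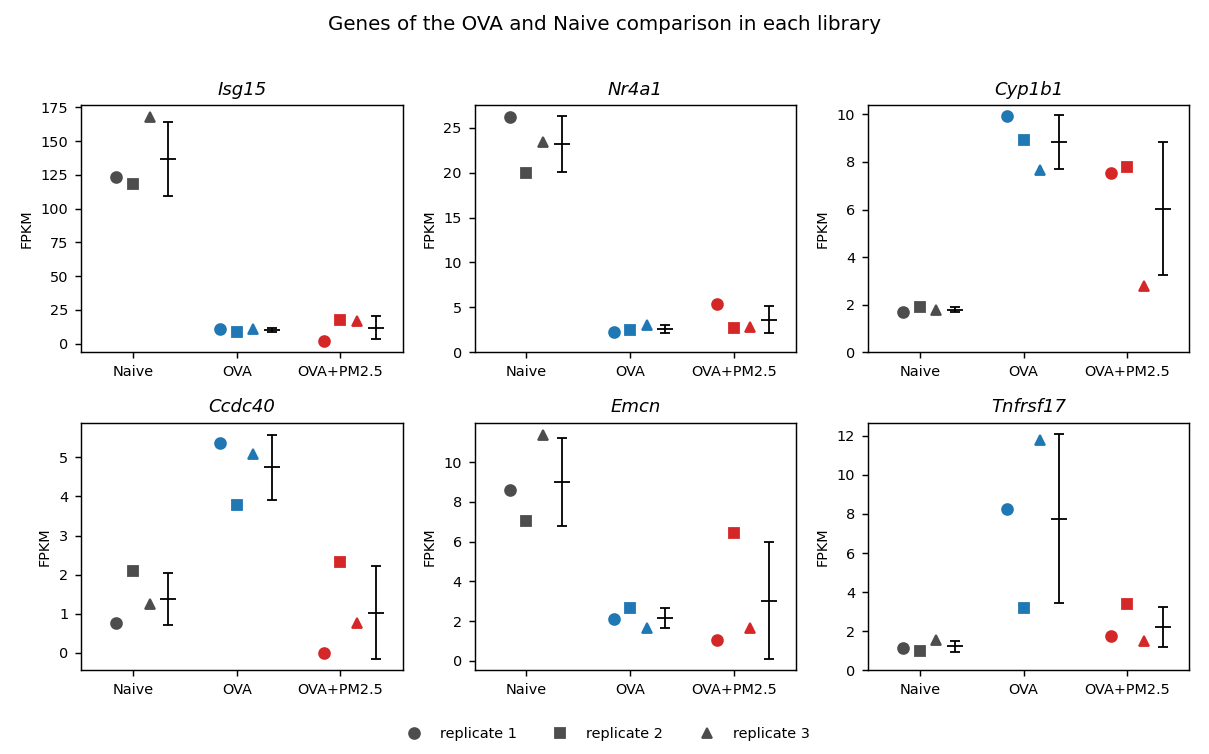
FPKM of Isg15, Nr4a1, Cyp1b1, Ccdc40, Emcn and Tnfrsf17 in Naive, OVA and OVA+PM2.5 lungs, 1 point per library with the group mean and SD. Nr4a1 fell from 23.2 to 2.57 FPKM between Naive and OVA.

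Particulate matter given on top of ovalbumin is used to model the worsening of asthma by air pollution. In these lungs mitochondrial, estrogen-related receptor and red cell lists stood higher and epithelial lists lower, calls of camera that were lost with an estimated correlation (adjusted p 0.267 or more). Muscle, heart and fat genes were higher in the same libraries, so each of these groups is given beside them. The muscle coregulator Perm1, a target of estrogen-related receptors, rose to 24.9 ± 18.5 FPKM from 0.859 ± 0.399 (log2 fold change 4.03, adjusted p 0.0223). The insulin-responsive glucose transporter Slc2a4, typical of muscle and fat, rose to 21.5 ± 8.90 from 0.963 ± 0.297 (3.82, adjusted p 0.0182).

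Perm1 and Slc2a4 belonged to 28 genes past an adjusted p of 0.05 with limma, 25 higher and 3 lower, against 3499 at an unadjusted p under 0.05. Simulated unchanged groups with each group's own SD gave a mean of 15.14 such genes. Their genes were drawn independently, while genes of the same tissue moved together in the real libraries. The simulation therefore cannot show how far chance counts range. The 2-group fit gave 0 in limma, with 2393 at an unadjusted p under 0.05. In 3495 genes (26.9%) the groups did not overlap, where 10% would on average by chance, a share that genes moving together can shift widely. Leaving out Naive replicate 1, 2 or 3, although Naive was not compared, left 0 genes in limma (3105, 2998 and 2963 unadjusted), as did OVA replicate 2 or 3 (2564 and 2423). The count was 11 without OVA replicate 1 (4 higher, 7 lower), 67 without OVA+PM2.5 replicate 1 (63 and 4), 3295 without replicate 2 (634 and 2661) and 201 without replicate 3 (194 and 7). At an unadjusted p under 0.05 with a fold of at least 2, 526 were higher and 1275 lower, so the direction of most calls depended on the library and the threshold. The median change over all genes was −0.23.

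Among the other higher genes, the adiponectin-receptor relative Paqr9 rose by 3.19 (adjusted p 0.0407), the sarcomere gene Lrrc39 by 3.11 (0.0329), the capillary gene Cd300lg by 2.83 (0.0329) and the pyruvate dehydrogenase subunit Pdha1 by 2.75 (0.0407). Lrrc39 stood at 6.20 ± 4.32 FPKM against 0.176 ± 0.0425 and Pdha1 at 94.2 ± 53.0 against 12.1 ± 1.73. The 3 lower genes were Topaz1 (−2.14, adjusted p 0.0329), Cnga2 (−1.80, 0.0328) and the membrane gene Shisal2a (−1.78, 0.0329). Topaz1 and Cnga2 stood at 0.0670 ± 0.116 and 0.0657 ± 0.0938 FPKM.

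Camera called 16 lists (8 up, 8 down) with the preset correlation and 0 with the estimated one, where adjusted p were 0.267 or more. Oxidative phosphorylation led (median 1.49, adjusted p 2.15e-25, 0.391 with the estimated correlation), with all 29 members positive, 2 rising and 22 rising adjusted over the list alone. The ATP synthase subunits Atp5b and Atp5a1 rose to 260 ± 90.4 from 57.8 ± 7.05 FPKM (2.11, adjusted p 0.0329) and to 242 ± 64.2 from 70.6 ± 8.07 (1.74, adjusted p 0.0425). Estrogen-related receptors and coactivators followed (median 1.63, adjusted p 1.89e-07, 0.267 with the estimated correlation), with 1 of 11 rising, 7 adjusted over the list alone, and the coactivator Ppargc1a at 3.55 ± 1.27 against 0.758 ± 0.0299 (1.63, adjusted p 0.0518). These genes are abundant in heart, skeletal muscle and brown fat, and Atp5b stood at 209, 207 and 364 FPKM in the libraries with skeletal muscle, atrial and brown fat transcripts. With replicate 2 alone, a single library whose medians are given without a test, the oxidative phosphorylation median was 1.24 and the estrogen-related receptor median 0.77, next to a cardiac median of 5.48.

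Cardiac muscle genes (median 2.38, adjusted p 1.3e-06, 0.558 with the estimated correlation), skeletal muscle genes (median 5.46, adjusted p 0.00237, 0.391) and adipose genes (median 4.33, adjusted p 8.52e-06, 0.492) were all called up. The skeletal muscle call rested on 3 of 9 members. Members could pass the filter through the libraries where they were high, so that call is not independent of the raised values. The creatine kinase Ckm stood at 357 ± 550 FPKM against 1.35 ± 2.09 (6.54, adjusted p 0.0743), the calcium pump regulator Sln at 5.86 (0.0898), Ckmt2 at 5.46 (0.0898) and Acta1 at 7.90 (0.118). The lipid droplet gene Plin4 stood at 10.6 ± 5.32 FPKM against 0.906 ± 0.181 (2.84, adjusted p 0.0518) and Ucp1 at 6.41 (0.0933). Erythrocyte genes were called up in the same libraries (median 3.52, adjusted p 1.39e-09, 0.391 with the estimated correlation). The haemoglobin gene Hba-a1 stood at 2593, 1914 and 5337 FPKM in replicates 1, 2 and 3 against 314 ± 267 in OVA (3.57, adjusted p 0.0608), and Hbb-bt at 3.95 (0.0608).

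Epithelial lists were lower, and mainly so in replicates 1 and 3, the libraries with skeletal muscle and brown fat transcripts. A response of lung cells thus cannot be told apart from a smaller share of lung there. Club cell markers (median −3.59, adjusted p 0.0126, 0.660 with the estimated correlation), alveolar type 2 markers (−2.67, 0.00541, 0.660), ciliated markers (−2.51, 0.000184, 0.660) and alveolar type 1 markers (−2.49, 0.00492, 0.660) were called down. With replicate 2 alone the medians were −0.44, −0.15, −0.64 and −0.39. Across all 3 libraries Sftpb averaged 200 ± 308 FPKM against 977 ± 179 (−4.10, adjusted p 0.1), and the collectin Sftpd stood at −3.22 (0.111). The sodium channel subunit Scnn1g stood at −3.81 (0.0935), the retinoid-induced Gprc5a at −3.34 (0.108) and Hp at −2.59 (0.113). The aldehyde dehydrogenase Aldh1a7 stood at −2.50 (0.113), Ccdc40 at −2.10 (0.0875) and Dnah9 at −1.92 (0.0899).

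Among defence and immune lists, neutrophil genes were called down (median −2.72, adjusted p 0.00541, 0.660 with the estimated correlation), with the gelatinase Mmp9 at −2.29 (adjusted p 0.0898) and the surface marker Ly6g at −3.28 (0.0951), and their median was −2.02 with replicate 2 alone. This rested on OVA replicates 2 and 3, since against the Naive mean the list median was −0.094, 3.18 and 4.65 in OVA replicates 1, 2 and 3 and −0.583, 0.71 and −0.162 in OVA+PM2.5. Xenobiotic genes (median −1.02, adjusted p 0.0404, 0.558 with the estimated correlation) included the oxygenase Cyp2b10 at −3.80 (0.0974). NRF2 genes (−0.78, 0.0467, 0.558) included the glutathione transferase Gsta3 at −1.82 (0.0845) and the haem oxygenase Hmox1 at −1.04 (0.0849), of 7 falling adjusted over the list alone. Type 2 cytokines and receptors (−0.71, 0.0460, 0.558) included Ccr8 at −1.70 (0.0768) and the IL-13 receptor Il13ra1 at −1.39 (0.0953). With replicate 2 alone the xenobiotic, NRF2 and type 2 medians were −0.67, −0.44 and −0.20. Against the Naive mean, xenobiotic medians were −1.46, −0.014 and −1.09 in OVA+PM2.5 replicates 1, 2 and 3. Club cell medians there were −5.68, 0.477 and −1.67. Alveolar macrophage markers were called up (median 0.37, adjusted p 0.0126, 0.558 with the estimated correlation), led by the lipase Lpl at 3.09 (0.0839), which fat and muscle also make, with Plet1 at −2.43 (0.0974), and had a median of −0.09 with replicate 2 alone. Proliferation genes were called up (median 0.43, adjusted p 0.0126, 0.773 with the estimated correlation), with Cdk1 at 0.44 (0.529) and the helicase subunit Mcm5 at 0.54 (0.537), and had a median of −0.26 with replicate 2 alone.

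The lists not called after particles had these medians. Type 2 chemokines stood at −0.52 (adjusted p 0.884), with Ccl12 at −1.49 (0.125), eosinophil markers at −0.72 (0.884), with the lipoxygenase Alox15 at 2.52 (0.0974), and mast cell markers at −1.27 (0.884), with Cma1 at 1.47 (0.0839). Goblet genes stood at 0.06 (0.884), with Galnt12 at −0.85 (0.126), alternatively activated macrophage genes at 0.12 (0.194), with the arginase Arg1 at 1.52 (0.151), and IL-17 genes at −0.75 (0.324), with the prostaglandin synthase Ptgs2 at −2.07 (0.0852). T cell markers stood at −0.60 (0.726), with the costimulator Icos at −1.08 (0.139), B and plasma cell markers at −0.37 (0.953), with the syndecan Sdc1 at −1.78 (0.0974), antigen presentation at −0.36 (0.884), with the dendritic lectin Clec9a at −1.50 (0.120), and interferon genes at −0.26 (0.973), with the antiviral Rsad2 at 1.89 (0.0609). Phosphodiesterases stood at −0.25 (0.756), with the cAMP-specific Pde7a at −0.70 (0.0849), and cAMP signalling at −0.02 (0.305), with the kinase subunit Prkaca at 1.18 (0.0738). Smooth muscle genes stood at −1.02 (0.467), with Actg2 at −1.87 (0.0852), fibrosis genes at −0.33 (0.977), with the tenascin Tnc at −0.93 (0.1), endothelial markers at −0.85 (0.216), with the adhesion molecule Esam at −1.26 (0.212), and thymus genes at 0.17 (0.328), with the follicle homing receptor Cxcr5 at 0.82 (0.351). Immediate early genes stood at −0.32 (0.884), with Ier2 at −1.11 (0.15), and clock genes at −0.58 (0.0949), with the period gene Per1 at −0.91 (0.0609). The median was below 0 and camera up for 6 lists: type 2 chemokines, eosinophil, interferon, phosphodiesterase, cAMP and immediate early genes, while goblet genes had a mean of −0.24. The sign of the median depended on the scaling for goblet, phosphodiesterase and cAMP genes.

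The 2 genes of the series title behaved differently from each other. Esrrg stood at 0.174 ± 0.0418 FPKM in Naive, 0.384 ± 0.0725 in OVA and 1.27 ± 0.572 in OVA+PM2.5, without overlap between any 2 groups. Its log2 fold changes were 0.39 for OVA against Naive (adjusted p 0.555), 0.96 for OVA+PM2.5 against OVA (0.0846) and 1.35 for OVA+PM2.5 against Naive (0.0296), and only the last passed the threshold, which it did not pass in the 2-group fit. Each OVA+PM2.5 library was above every OVA library, at 1.93, 1.00 and 0.880 FPKM, and each also carried a raised muscle, cardiac or fat list. Pde3b stood at 2.77 ± 0.258, 3.53 ± 0.914 and 10.5 ± 12.3 FPKM, with log2 fold changes of 0.28 (adjusted p 0.908), 0.81 (0.478) and 1.09 (0.289). Its 3 OVA+PM2.5 values were 5.07, 1.87 and 24.6 FPKM, the highest in the library with brown fat transcripts, a tissue where Pde3b mediates insulin action on lipolysis. Without replicate 3 the Pde3b change between OVA and OVA+PM2.5 was −0.12, and without replicate 2 it was 1.58.

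**Figure D3:**
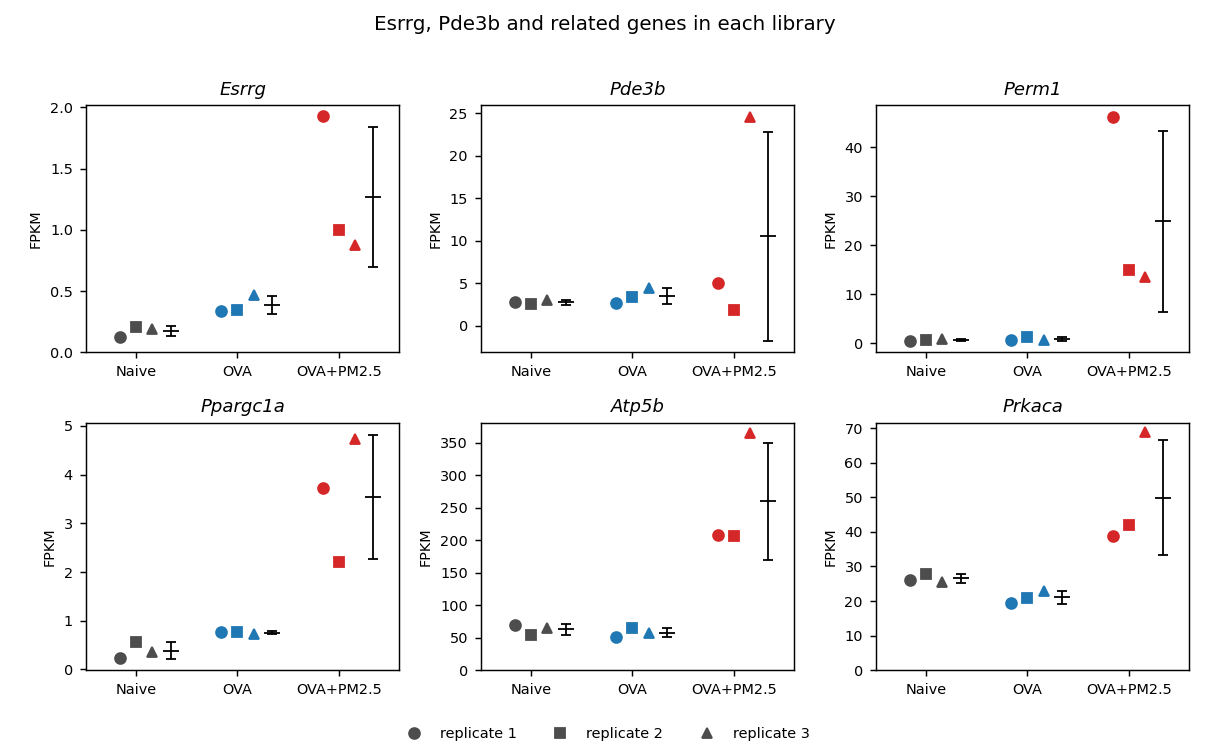
FPKM of Esrrg, Pde3b, Perm1, Ppargc1a, Atp5b and Prkaca in Naive, OVA and OVA+PM2.5 lungs, 1 point per library with the group mean and SD. Esrrg averaged 0.174, 0.384 and 1.27 FPKM and Pde3b 2.77, 3.53 and 10.5 FPKM.

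The direct comparison with Naive lungs takes ovalbumin and particles together. Interferon-induced, immediate early and alveolar lists stood lower and plasma cell, mitochondrial and estrogen-related receptor lists higher, beside the muscle, heart and fat lists. Camera called these lists with the preset correlation and none with the estimated one (adjusted p 0.246 or more). The cytotoxic granule protease Gzma fell to 2.07 ± 2.11 FPKM from 59.5 ± 28.8 (log2 fold change −4.85, adjusted p 0.0221), and Nr4a1 fell to 3.61 ± 1.52 from 23.2 ± 3.09 (−2.58, adjusted p 0.0156).

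With limma 924 genes passed, Gzma and Nr4a1 among them, 198 higher and 726 lower (737 changed at least 2-fold), against 4488 at an unadjusted p under 0.05. Simulated unchanged groups, again with independent genes, gave a mean of 12.76, which cannot show how far chance counts range. The 2-group fit gave 0 in limma, with 3594 unadjusted. In 5203 genes (40.1%) the groups did not overlap, where 10% would on average by chance, a share that genes moving together can shift widely. The higher share depended on scaling and on the libraries kept. It was 21.4% as deposited, 52.9% (184 higher, 164 lower) after median-ratio scaling and 53.5% (209 and 182) after quantile normalization. After rescaling to a common sum it was 13.3% (187 and 1222). The median change over all genes was −0.33 as deposited. Leaving out Naive replicate 1, 2 or 3 left 0 in limma (3009, 3389 and 3252 unadjusted), and OVA replicates 1, 2 and 3 left 52, 38 and 43. Without OVA+PM2.5 replicate 1, 2 or 3 the counts were 143 (77 higher, 66 lower), 4248 (695 and 3553) and 418 (240 and 178).

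Among genes past the threshold, the 6 named for the largest increases are known from muscle. Ckm rose by 6.36 (adjusted p 0.0397), the oxygen carrier Mb by 5.98 (0.0340), the elongation factor Eef1a2 by 5.79 (0.0452), Tmem182 by 5.56 (0.0293), the sarcomere stabiliser Klhl41 by 5.54 (0.0427) and Apobec2 by 5.39 (0.0293). Mb stood at 112 ± 92.0 FPKM against 0.706 ± 0.994. Besides Gzma, the methyltransferase Inmt (−4.73, adjusted p 0.0447), the alveolar claudin Cldn18 (−4.10, 0.04999), the lipofibroblast factor Tcf21 (−4.09, 0.0482), Bex4 (−3.99, 0.0397) and the mesenchymal factor Foxf1 (−3.98, 0.0393) had the largest decreases past the threshold. Inmt stood at 173 ± 268 FPKM against 1437 ± 213 and Foxf1 at 17.3 ± 23.9 against 139 ± 11.1. Such decreases cannot be told apart from a smaller share of lung in the OVA+PM2.5 libraries.

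Camera called 15 lists (10 up, 5 down) with the preset correlation and 0 with the estimated one, where adjusted p were 0.246 or more. Interferon genes were lower (median −2.09, adjusted p 5.84e-06, 0.332 with the estimated correlation), with 13 of 16 members falling, and a median of −1.70 with replicate 2 alone. The oligoadenylate synthetase-like Oasl2 fell to 2.28 ± 1.03 FPKM from 21.1 ± 6.24 (−3, adjusted p 0.0156) and Ifi44 to 1.97 ± 0.933 from 16.7 ± 4.98 (−2.83, adjusted p 0.0181). Immediate early genes were lower (median −1.86, adjusted p 0.00159, 0.332 with the estimated correlation), with 6 of 11 falling, Egr1 among them (−2.08, adjusted p 0.0264). The clock list was not called by camera (median −0.95, adjusted p 0.112) but was by fry (adjusted p 0.0169). Of its members 4 of 13 fell, including Per1 (2.07 ± 0.129 FPKM against 6.44 ± 0.520, −1.43, adjusted p 0.0156) and Ciart (−1.58, adjusted p 0.0264).

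Oxidative phosphorylation (median 1.20, adjusted p 2.4e-20, 0.332 with the estimated correlation) had 12 of 29 members rising, with Atp5b at 2.00 (adjusted p 0.0238) and Atp5a1 at 1.71 (0.0248). Estrogen-related receptor genes (median 1.35, adjusted p 1.54e-07, 0.246 with the estimated correlation) had 5 of 11 rising, with Perm1 at 4.18 (0.0156) and Ppargc1a at 2.16 (0.0156). Cardiac (median 2.04, adjusted p 6.83e-07, 0.332), skeletal muscle (4.82, 0.00232, 0.332), adipose (3.55, 1.61e-05, 0.332), and erythrocyte genes (1.76, 2.21e-05, 0.332) were called up in the same libraries. The list of thymus and lymphoid tissue genes was also called up (0.92, 0.0393, 0.398), with a median of −0.22 with replicate 2 alone. It rested on 3 of 9 members, Cxcl13 and Cxcr5 among them. In Naive replicate 1, the library with thymus genes, the list median against the Naive mean was −0.089. In each OVA+PM2.5 library 0 of 9 members were raised over 10-fold, so this call does not show thymus tissue there. Plin4 rose by 3.21 (0.0248) and the haem synthesis enzyme Alas2 by 2.61 (0.0467), while Sln stood at 5.11 (0.0686), Ckmt2 at 4.82 (0.0689), Acta1 at 7.41 (0.0962), Ucp1 at 5.80 (0.0699), Hba-a1 at 2.17 (0.0615), Cxcl13 at 2.23 (0.104) and Cxcr5 at 0.92 (0.250).

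Immune lists called up were B and plasma cell markers (median 0.91, adjusted p 0.000149, 0.332 with the estimated correlation), alveolar macrophage markers (0.40, 0.00185, 0.332) and alternatively activated macrophage genes (0.15, 0.0262, 0.332). With replicate 2 alone their medians were 0.19, −0.09 and −0.11. Jchain rose to 327 ± 187 FPKM from 27.2 ± 3.02 (3.35, adjusted p 0.0293), and the B cell coactivator Pou2af1 stood at 2.19 (0.0593). Lpl rose by 3.85 (0.0340), with Ctsk at 1.13 (0.0928), and the resistin-like Retnla stood at 229 ± 178 FPKM against 20.5 ± 9.91 (2.97, 0.121), with Cd200r1 at 0.65 (0.152). Lists called down were alveolar type 1 (median −3.05, adjusted p 0.00261, 0.530 with the estimated correlation), alveolar type 2 (−3.19, 0.00441, 0.530) and endothelial markers (−2.02, 0.00232, 0.530). The type 1 gene Rtkn2 (−2.6, 0.0452) and Esam (−2.43, 0.0473) fell, while Aqp5 stood at −3.30 (0.0536), Lpcat1 at −2.68 (0.0537), Napsa at −2.76 (0.0563) and Egfl7 at −2.52 (0.0537). The medians of these 3 lower lists with replicate 2 alone were −0.89, −0.82 and −0.60.

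Several lists that camera did not call held members past the threshold. Of phosphodiesterases (median −0.24, adjusted p 0.676), Pde5a (−2.38, 0.0377) and Pde8b (−1.47, 0.0431) fell. Of cAMP signalling genes (−0.35, 0.935), 4 of 23 fell, including Adcy8 (−1.77, 0.0340). Of fibrosis genes (−1.09, 0.235), 3 of 17 fell, including periostin, Postn (−1.85, 0.0340). Of type 2 cytokines and receptors (−0.78, 0.105), the epithelial alarmin Tslp fell (−1.85, 0.0385), with Areg at −2.24 (0.0521). Zbtb46 (−1, 0.0415) and Clec9a (−2.22, 0.0438) fell among antigen presentation genes (−1.13, 0.105). Cyp1b1 rose by 1.40 (0.0452) among xenobiotic genes (−0.30, 0.685), with Ahr at −1.45 (0.0520), and Srxn1 by 0.91 (0.0438) and Sod2 by 1.16 (0.0454) among NRF2 genes (−0.15, 0.225), of which 2 of 19 rose and 1 fell. The eosinophil ribonuclease Ear1 fell (−2.66, 0.0431), with Ear2 at −2.93 (0.0988; list median 0.59, 0.326). The stem cell factor receptor Kit fell (−2, 0.0473), with Cma1 at −1.04 (0.0814; list median −1.27, 0.225). With replicate 2 alone the falls were smaller: Pde5a −1.38, Pde8b −0.66, Adcy8 −0.97, Postn −1.30, Tslp −1.09, Zbtb46 −0.59, Clec9a −0.90, Ear1 −1.03 and Kit −0.77. None of these genes passed in the 2-group fit. Such decreases cannot be told apart from a smaller share of lung in replicates 1 and 3.

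The other lists held no member past the threshold against Naive. Their medians were 0.08 for type 2 chemokines (adjusted p 0.326), with Ccl12 at −1.83 (0.0610), 0.55 for goblet genes (0.0556), with Slc26a4 at 1.76 (0.102), −0.03 for neutrophil genes (0.123), with Csf3r at −0.86 (0.287), and −0.42 for IL-17 genes (0.935), with Ptgs2 at −1.92 (0.0566). They were −1.38 for T cell markers (0.499), with Cd3d at −1.97 (0.202), −0.68 for smooth muscle (0.752), with Mylk at −1.52 (0.0699), and −0.72 for proliferation (0.411), with Pcna at −1.14 (0.0622). Club and ciliated markers stood at −2.03 (0.326) and −1.24 (0.466), with Cbr2 at −3.31 (0.157) and Tppp3 at −1.42 (0.0931), and with replicate 2 alone their medians were 0.48 and 0.67. The median was below 0 and camera up for 6 lists: neutrophil, xenobiotic, NRF2, phosphodiesterase, cAMP and smooth muscle genes, while eosinophil genes and type 2 chemokines, also up in camera, had means of −0.44 and −0.30. The sign of the median depended on the scaling for type 2 chemokines, neutrophil, xenobiotic, NRF2 and phosphodiesterase genes.

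Across the 3 groups, the limma F-test called 91 of 12982 genes. Ncr1 and Nr4a1 were lower in both OVA and OVA+PM2.5 than in Naive, the 2 shared calls, where independent lists would share 0.11 and simulated unchanged groups shared a mean of 0.08 and at most 3. The change from Naive to OVA and the change from OVA to OVA+PM2.5 correlated at −0.301 over genes. The OVA libraries enter both changes with opposite sign, and simulated unchanged groups gave a mean of −0.34, between −0.389 and −0.294. The covariance was −0.14 against a simulated mean of −0.051 (−0.06 to −0.042), outside the simulated range. The 2 changes from Naive correlated at 0.344 against a simulated mean of 0.25 (0.203 to 0.293), with a covariance of 0.163 against 0.036 (0.03 to 0.044). The simulated groups share the Naive libraries but hold no effects, and their genes were drawn independently. Their ranges are therefore too narrow for genes that move together, and part of that excess may still come from the shared Naive libraries. Groups of 3 cannot be divided into control sets of at least 2 libraries each to check this.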

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

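The voom fit, the fit with replicate 2 as the only OVA+PM2.5 library, the weights per group and the 2-group fit without Naive replicate 1 were added after the results had been seen, and the other alternatives were planned before. Counts below are genes past the threshold in OVA against Naive (2 in the 9-library fit), OVA+PM2.5 against OVA (28) and OVA+PM2.5 against Naive (924), then the F-test (91) and shared calls (2). Of 4347 fold changes of the named genes under alternatives, 3404 kept direction and side, 652 lost the threshold, 279 gained it and 12 turned direction. Most of these genes were named for large changes or small p in the same libraries, so few reversals could occur. By another criterion, 103 of 211 counts and correlations moved by more than 1.5 times or 1 SD.

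A pseudocount of 0.1 gave 1 gene after OVA, 488 in OVA+PM2.5 against Naive and 1 shared call, and a pseudocount of 1 gave 20 after OVA, 147 in the F-test and 18 shared. Without a filter the counts were 0 (1800 unadjusted), 12 and 157, with 45 in the F-test and 0 shared, and a filter at FPKM 1 gave 50 in OVA+PM2.5 against OVA. Median-ratio scaling gave 103 in OVA+PM2.5 against OVA and 348 in OVA+PM2.5 against Naive. Rescaling to a common sum gave 29, 93 and 1409, with 223 in the F-test, 28 shared and 20 lists after OVA, and the Pde3b change after OVA became −0.07. Quantile normalization gave 18, 138 and 391, with 198 in the F-test and 15 shared.

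Array weights gave 1277 genes after OVA, 0 in OVA+PM2.5 against OVA in limma (2874 unadjusted), 1608 in the F-test and 259 shared. One weight per group gave 817, 7 and 473, with 1089 in the F-test and 157 shared. With the replicate number as a block, a paired fit, the counts were 0 (1331 unadjusted), 0 (3169 unadjusted) and 50, with 0 in the F-test and 0 shared. The 2-group fit gave 895, 0 (2393 unadjusted) and 0 (3594 unadjusted), and 37 after OVA without Naive replicate 1. Voom on recovered fragments gave 143 in OVA+PM2.5 against Naive and a correlation of −0.378 between the 2 steps. Camera with the estimated correlation called 0, 0 and 0 lists. An unadjusted p under 0.05 with a fold of at least 2 gave 610, 1801 and 2090.

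With replicate 2 as the only OVA+PM2.5 library the counts were 887, 253 and 333, with 754 in the F-test, 72 shared and 7 lists in OVA+PM2.5 against OVA. A single library has no spread of its own, so these counts rest on the spread of the Naive and OVA libraries and leave out that of the widest group. Against OVA, Pde3b turned to −0.74, Esam to 0.14, Cdk1 to −0.13 and Cxcr5 to −0.32, and against Naive, Pde3b turned to −0.46, Cbr2 to 0.27 and Cxcr5 to −0.22.

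Leaving out 1 library at a time moved the counts from 0 to 54 after OVA, from 0 to 3295 in OVA+PM2.5 against OVA and from 0 to 4248 in OVA+PM2.5 against Naive. The count was 0 without any 1 of the Naive libraries in all 3 comparisons (744, 3105 and 3009 unadjusted without Naive replicate 1) and without OVA replicate 2 or 3 in the first 2, and highest without OVA+PM2.5 replicate 2. The F-test moved from 0 to 3991 and shared calls from 0 to 42. The correlation of the 2 steps moved from −0.377 without OVA replicate 2 to −0.251 without OVA+PM2.5 replicate 2. Ckmt2 after OVA moved from −2.05 without OVA replicate 2 to 0.55 without Naive replicate 3, and Pde3b in OVA+PM2.5 against OVA from −0.12 without OVA+PM2.5 replicate 3 to 1.58 without replicate 2.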

Other observations

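The genes of this part, and the tests of tissue, scaling, Pde3b, Esrrg and interferon, were chosen after the values had been seen, while the regroupings of libraries were planned before.

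Beside Ncr1, 5 further genes, each picked for its values and not tested as a group, stood lower in both ovalbumin groups than in Naive. The granzyme Gzmb stood at 11.2 ± 3.62 FPKM in Naive, 0.649 ± 0.204 in OVA and 0.871 ± 0.920 in OVA+PM2.5 (OVA against Naive −3.31, adjusted p 0.0768, OVA+PM2.5 against Naive −3.30, 0.0264). The pore-forming Prf1 stood at −2.41 (adjusted p 0.0836) and −2.38 (0.0293) in the same comparisons, Gzma at −5.19 (0.0570) and −4.85 (0.0221), the granule protein Nkg7 at −1.87 (0.316) and −2.59 (0.0431), and the lectin receptor Klre1 at −1.37 (0.190) and −1.30 (0.0431). Between OVA and OVA+PM2.5, the log2 fold changes were 0.01 for Gzmb (0.993), 0.03 for Prf1 (0.974), 0.34 for Gzma (0.771), −0.72 for Nkg7 (0.454) and 0.06 for Klre1 (0.911).

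Transcripts of 2 secreted airway proteins were found mainly in 2 of the 3 OVA+PM2.5 lungs. The goblet cell protein Clca1 stood at 0, 14.3 and 18.7 FPKM in OVA+PM2.5 replicates 1, 2 and 3 and at no more than 0.461 in any Naive or OVA library. The chitinase-like Chil4 stood at 0.0749, 3.95 and 27.3 FPKM, against 0 in all OVA libraries and at most 0.0226 in Naive. Both fell below the expression filter and were not tested. The resistin-like Retnla did not share this pattern, at 32.3, 380 and 275 FPKM in OVA+PM2.5 and 78.5, 21.2 and 482 in OVA, its highest value. The replicate without Clca1 was the one in which the club cell gene Scgb1a1 stood at 12.0 FPKM, against 83190 and 6131 in the others.

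The muscle, heart and fat transcripts likely came from tissue sampled along with lung or in its place. The highest share of an other-tissue list raised over 10-fold was 88.9%, and a different list led in each library. Of the genes raised over 10-fold, 0.3% were raised in all 3, which argues against 1 response shared by the 3 mice as the source of most of them. A shared response below 10-fold, or one mixed with other tissue, would not be seen by this count and is not excluded. Scaling was excluded as a source of rises over 10-fold, with a lowest median-ratio factor of 0.813. Cardiac muscle surrounds mouse pulmonary veins, and Myl7 reached 130 FPKM in Naive replicate 3 and 154 in OVA replicate 2, so more of the heart end of the vein in OVA+PM2.5 replicate 2 could account for 2650.

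Esrrg and Pde3b may reflect the same tissues. Pde3b was above the highest OVA library in 2 of 3 OVA+PM2.5 libraries, so a rise was not seen in every library. With replicate 2 as the only library its change from OVA was −0.74. That library also held cardiac transcripts, so the values cannot decide whether Pde3b rose in the lung of every mouse. For Esrrg the data cannot separate lung from other tissue, since 0 OVA+PM2.5 libraries were without a raised list. A measurement in dissected lung or in sorted lung cells could decide it.

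The lower interferon genes after OVA did not rest on Naive replicate 1, because without it the list median was −1.66. Other libraries were not left out for this value. Against the Naive mean, list medians were −1.54, −1.93 and −1.58 in OVA replicates 1, 2 and 3. They were −0.222, −0.161 and 0.448 in Naive replicates 1, 2 and 3, so each OVA library lay below each Naive library. Dilution by Scgb1a1 was excluded, since it took at most 9.79% of OVA fragments and a 2-fold dilution would need over 50%. A difference in handling or time of collection could not be excluded, with immediate early genes at a median of −1.19. An infection or a housing difference among Naive mice might also raise interferon and cytotoxic genes there, and no measurement here tests it.

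Regrouping the libraries gave these values. For comparisons of 3 against 3 there are 10 splits, too few for a share under 0.05. The labelled split gave 2 genes after OVA against at most 0 in any other (1 of 10 as large), 895 against 0 in the 2-group fit (1 of 10), 28 against 0 in OVA+PM2.5 against OVA (1 of 10) and 924 against 0 in OVA+PM2.5 against Naive (1 of 10). Lists called were 13 against at most 20 (3 of 10), 16 against 15 (1 of 10) and 15 against 15 (4 of 10). Among 100 drawn splits of 9 libraries, the F-test gave 91 genes against at most 4 (1 of 100) and shared calls were 2 against at most 3 (3 of 100). For the F-test the labelled grouping stood out from the drawn ones, with a share under 0.05, for the full set of libraries only. Its count was 0 without any 1 of the Naive libraries and without OVA replicate 2 or 3. Regrouping mixes libraries of narrow and wide groups, so their unequal spread may enter this result. The share for shared calls is also under 0.05, but that count was 0 in the same fits. Simulated unchanged groups also reached 3 shared calls, so the 2 are not taken as established. The correlation of −0.301 was reached or passed in 81 of 100, with −0.936 as the lowest, so chance was not excluded for the correlation. The covariance of the 2 steps (−0.14) lay outside the range of simulated unchanged groups (−0.06 to −0.042). That range came from genes drawn independently and is too narrow for genes that move together, so it does not exclude chance either.

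The labels give all mice as male. Of 8 Y-linked genes in the table, 6 were at 0 in all 9 libraries, and the highest FPKM of any was 0.025, with values above 0 in 2 libraries. Kdm5d stood at 0.00623 FPKM in OVA replicate 1 and Eif2s3y at 0.02499 in OVA replicate 2, so both were quantified. Leaving the other genes out of the quantification would not account for values this low in these 2. The values go against the label, and the sex of the mice stays open.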
